A study of Mus musculus with 6 samples.

How the data were processed

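Single-cell RNA sequencing was done on CD4+ T cells sorted by flow cytometry from spleen and from vascular tissue of C57/B6 mice with an elastase-induced abdominal aortic aneurysm, a model in which elastase brought to the infrarenal aorta weakens its wall. Per the labels' protocols, mice were 8 to 12 weeks old and were killed 14 days after surgery. The whole aorta was minced and digested with enzymes for 1 h at 37 °C, whereas the spleen was ground without digestion. Both suspensions were strained and passed through a density gradient before the sort, and about 10000 cells were loaded per channel of a droplet instrument that captures the 5' end of transcripts, with a target of about 6000. Enzymatic digestion, tissue of origin and time outside the animal therefore varied together. All 6 libraries came from treated mice, 3 from spleen and 3 from vascular tissue, and no sample of untreated aorta was analysed here.

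The labels give replicate numbers 1 to 3 in both tissues and do not say whether replicates were separate animals or whether equal numbers mark the same animals. The p-values therefore measure the spread between these libraries, which may be technical. Per the submitters' processing notes, reads were checked with FastQC 0.11.8, aligned to mm10 with STAR 2.5.1b inside Cell Ranger 2.2.0 and handled with Seurat, whose version is not given in the sources used here. The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, per the file headers, with no normalization. They list 27998 genes. Constant regions of the T cell receptor were not found among them under the symbols of the marker lists, so receptor chains were not used to name cells.

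The unit of every test was the library. Choices of lists, markers, tests and alternatives were made before the data were examined, except those named below and in the closing section. Cells with at least 300 genes and at most 10% mitochondrial UMIs were kept. Doublets were scored per library by the share of simulated doublets (2 per cell) among each cell's neighbours, and the cells with the highest scores, 0.8% for each 1000 barcodes of the library, were removed. Clustering ran in 2 steps, over all cells and then over T-like cells alone. Counts were scaled to 10000 per cell, log-transformed and reduced to 2000 variable genes and 30 principal components. Cells were joined to 15 nearest neighbours and split with the Leiden method at resolution 1. Mitochondrial, ribosomal, immunoglobulin and T cell receptor genes and the immediate early and heat shock lists were kept out of the variable genes.

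Clusters were named from marker lists of 15 other cell types (B cell, plasma cell, macrophage or monocyte, dendritic cell, neutrophil, mast cell or basophil, NK or ILC, CD8 T, gamma delta T, smooth muscle, fibroblast, endothelial, adipocyte, erythroid and platelet) and of T cell subsets. The thresholds for a name were set after the clusters had been seen. A T-like cluster had a Cd3e UMI in at least 80% of cells and fewer than 3 markers of another lineage among its top 10 genes by fold. A subset name needed a mean log2 fold of at least 0.5 and at least 3 markers, each seen in at least 5% of cells, and a Foxp3 UMI in over 50% of cells allowed no name but regulatory T cell (Treg). A name ending in "-like" rests on these markers alone.

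For each class, UMIs were summed per library over its cells, a library with under 20 cells of the class being left out. The sums were tested with the quasi-likelihood test of edgeR 4.0.16 (TMM normalization, filterByExpr, tissue as the only term, two-sided, Benjamini-Hochberg adjustment at 0.05). Log2 differences are vascular minus spleen, with SE taken as the log2 difference divided by the square root of F. Adjusted p-values for single genes come from edgeR. Differences between classes were tested as a class by tissue interaction with library as a block. Levels are CPM, counts scaled by library size, of the class sums with TMM-scaled library sizes, given as mean ± SD over libraries. Within a class, a fold against 0 UMIs used a floor of 3 counts over the group and is written "at least", and one against 1 to 3 UMIs is given as a ratio with its 95% counting interval.

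There were 22 gene lists: naive and recirculation, tissue residency, immediate early response, heat shock, T cell activation, inhibitory receptors, Th1, Th17, Th2, Tfh, Treg core, tissue Treg, cytotoxicity, chemokine receptors, cytokines, type I interferon response, proliferation, glycolysis and hypoxia, oxidative phosphorylation, migration and adhesion, lipid handling, and apoptosis. They were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the lists, and again with an estimated correlation and with fry. A member count is given over all genes tested and adjusted over the list alone. Shares of cells were compared by an exact two-sided permutation test of the difference in means. With 3 libraries against 3 this exact test cannot go below p = 0.1. Shares of cells with a UMI of a gene were compared after each cell had been thinned to 1000 UMIs, for 11 genes planned and 3 added after the data had been seen, of which 2 are reported. Counting intervals, which are exact binomial ones, and floors cover counting error only.

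Named genes followed a fixed rule: adjusted p under 0.05, a mean of at least 32 CPM and no overlap between the tissues, then the 8 largest rises and 8 largest falls in all T-like cells and the 5 and 5 in each class and interaction (for interactions without the overlap condition). Genes named Gm or ending in Rik, and mitochondrial, ribosomal, immunoglobulin, T cell receptor and haemoglobin genes were left out of this ranking. From each list the rule took the 2 members with the smallest p and 1 in the other direction in all T-like cells, and Cd4, Cd3e, Cd8a, Foxp3, Cd44, Cd69, Ifng, Il17a and Il10 were always taken. Some genes that these rules took are not reported here. The same choice of list members was applied within the 3 classes after the values had been seen. Positions come from GENCODE vM21 on GRCm38 (mm10). All 142 gene identifiers looked up were found there.

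Near-identical genes such as Hspa1a and Hspa1b, Ly6c1 and Ly6c2, the Bcl2a1 family and the Ifitm family could share reads, so a value of any 1 of them is uncertain. The edgeR and DESeq2 fits were run first on simulated counts with 200 changed genes, rises and falls in equal number. Far more genes passed in the data of all T-like, naive-T-like and Treg-like cells, so the rates may not carry over. List tests were run with only the heat shock list raised and genes drawn independently, which cannot test the preset correlation. The exact tests of shares were not simulated. In all T-like cells edgeR recovered 81.4% of genes changed by a log2 of 1 and all of those changed by 2. In effector-or-memory-T-like cells, which had fewer spleen cells and 2 spleen libraries, it recovered 22.2% and 55.3%. False calls made up 9.28% of calls in all T-like, 7.37% in naive-T-like, 7.73% in Treg-like and 2.63% in effector-or-memory-T-like cells, so the first 3 lay above the 5% aimed at. With DESeq2 the share was highest, at 26.8%, for the comparison of Treg-like with effector-or-memory-T-like cells, and it was 17.8% in all T-like cells. The alternatives tried were DESeq2 1.42.0, another normalization (RLE), no filter on low counts, the replicate number as a block, leaving out each library, stricter cell filters (500 genes, 5% mitochondrial), no doublet removal, Leiden resolutions 2 and 0.5, genes centred within each library before clustering, equal cell numbers per library, cells with a UMI of Cd4 and none of Cd8a or Cd8b1, other correlations for the lists, and thinning to 2000 UMIs or none. Leaving out doubted clusters or gene lists was chosen after seeing the data. Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2) and R 4.3.3 were used.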

Results

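The series compares CD4+ T cells of the vascular tissue with CD4+ T cells of the spleen in mice with an elastase-induced aneurysm of the abdominal aorta, to describe the diversity of these cells. The 6 libraries held 41315 barcodes and 240821626 UMIs. Spleen libraries 1 to 3 held 2312, 9384 and 9581 barcodes with 14836442, 55341817 and 55483411 UMIs. Vascular libraries 1 to 3 held 8662, 4962 and 6414 barcodes with 46875431, 28986221 and 39298304 UMIs. The median depth per barcode ran from 4423 to 5724 UMIs. The cell filters kept 41303 barcodes, 2607 were then removed as doublets, and 38696 cells remained. Mitochondrial UMIs took a median of 2.11% ± 0.184 in spleen and 1.37% ± 0.079 in vascular libraries, and ribosomal protein genes took 38.7% ± 0.882 and 31.0% ± 2.06 (SD, n = 3, exact p = 0.1 for both, the smallest this design allows). Counts of replicate libraries differed by more than sampling noise in every pair, with chi-square per degree of freedom from 13.1 to 44.1.

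T-like cells made up 93.6% ± 0.421 of the cells kept in spleen and 91.3% ± 1.41 in vascular tissue (SD, n = 3, exact p = 0.1). Among the others, cells like dendritic cells, led by Siglech, Klk1 and Irf8, took 0.842% ± 0.225 in spleen and 5.95% ± 1.22 in vascular tissue. Siglech is a surface receptor of plasmacytoid dendritic cells and Irf8 a transcription factor they need. B cell-like cells took 1.14% ± 0.0816 and 0.676% ± 0.360 (exact p = 0.2). Cells with Cd3e that also carried C1qa, C1qb, C1qc and Apoe, genes of macrophages, took 3.11% ± 0.365 and 1.51% ± 0.291, and non-T cells left unnamed took 1.29% ± 0.25 and 0.611% ± 0.0532 (exact p = 0.1 for both). These cells, 2929 in all, were kept out of the comparisons of T cells, which rest on 35767 T-like cells with library medians of 4173 to 5614 UMIs.

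Naive-T-like cells took the largest share in spleen and effector-or-memory-T-like cells the largest mean share in vascular tissue. The naive-T-like share was 43.2% ± 1.31 of T-like cells in spleen and 19.0% ± 11.1 in vascular tissue, where the 3 libraries lay at 8.14%, 18.5% and 30.4%. Effector-or-memory-T-like cells, with Ifng and Cxcr6 among their leading genes, took 0.578% ± 0.0922 and 36.1% ± 12.8, and in vascular library 3 they lay at 22.4%, below the naive-T-like cells. Cytotoxic T-like cells, led by the granzyme gene Gzmk and the chemokine genes Ccl4 and Ccl5, took 0.0368% ± 0.0446 and 11.3% ± 3.02. None were seen among 2115 T-like cells of spleen library 1, which allows a share of up to 0.142%. Th17-like cells took 0.673% ± 0.132 and 4.59% ± 1.67, and Th2-like cells 0.0436% ± 0.0445 and 3.07% ± 0.577. The Th2-like cluster was led by Ccl1, Dusp14, Csf2, Penk and Il2 rather than by Th2 cytokines, with a Gata3 UMI in 57.7% and an Il13 UMI in 6.70% of its cells.

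Treg-like cells took 11.6% ± 0.885 of T-like cells in spleen and 8.32% ± 0.675 in vascular tissue, interferon-responsive T-like cells 10.2% ± 0.816 and 6.47% ± 1.75, and cells like follicular helper T cells (Tfh) 4.95% ± 0.141 and 1.27% ± 1.08. Cycling-like cells took 2.05% ± 0.227 and 2.56% ± 0.510 (exact p = 0.2), and unnamed T-like clusters 26.7% ± 1.27 and 7.34% ± 1.92. For 9 of the 10 classes the libraries of the tissues did not overlap (exact p = 0.1, adjusted p = 0.111), and no share could reach p under 0.05 with 3 libraries a side. With a finer clustering the Tfh-like share turned to 5.23% in spleen and 9.65% in vascular tissue, and it was 19.6% and 3.36% with a coarser one. With genes centred per library it was 4.49% and 2.94%, and the libraries overlapped (exact p = 0.2). The Th2-like share of vascular cells was 1.60% with the finer clustering, and no cluster had this name with the centred one. The cytotoxic share of vascular cells was 0.388% without doublet removal and 4.55% with the finer clustering, no cluster had this name with the coarser one, and the spleen share was 2.47% with the centred one. The effector-or-memory share of spleen cells was 2.27% with the finer and 0.112% with the centred clustering. With the coarser clustering the Treg-like shares were 11.6% and 10.2% and overlapped (exact p = 0.2). The unnamed share rests on name thresholds set after the clusters had been seen. The largest unnamed cluster took 16.0% in spleen and 2.49% in vascular tissue. It had a Gata3 UMI in 30.9%, Il2 in 6.81% and Cxcr5 in 14.6% of cells. These were 29.1%, 7.12% and 0.489% in the effector-or-memory cluster with spleen cells, and 18.2%, 0.0600% and 0.210% in the largest naive-T-like one. Whether cells of the unnamed cluster were antigen-experienced was not tested. Other unnamed clusters included 1 with Klrb1c, Il4 and Zbtb16 (2.57% in spleen and 0.120% in vascular tissue) and 1 with Foxp3 and Itgae (0.0920% and 1.86%).

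**Figure D1:**
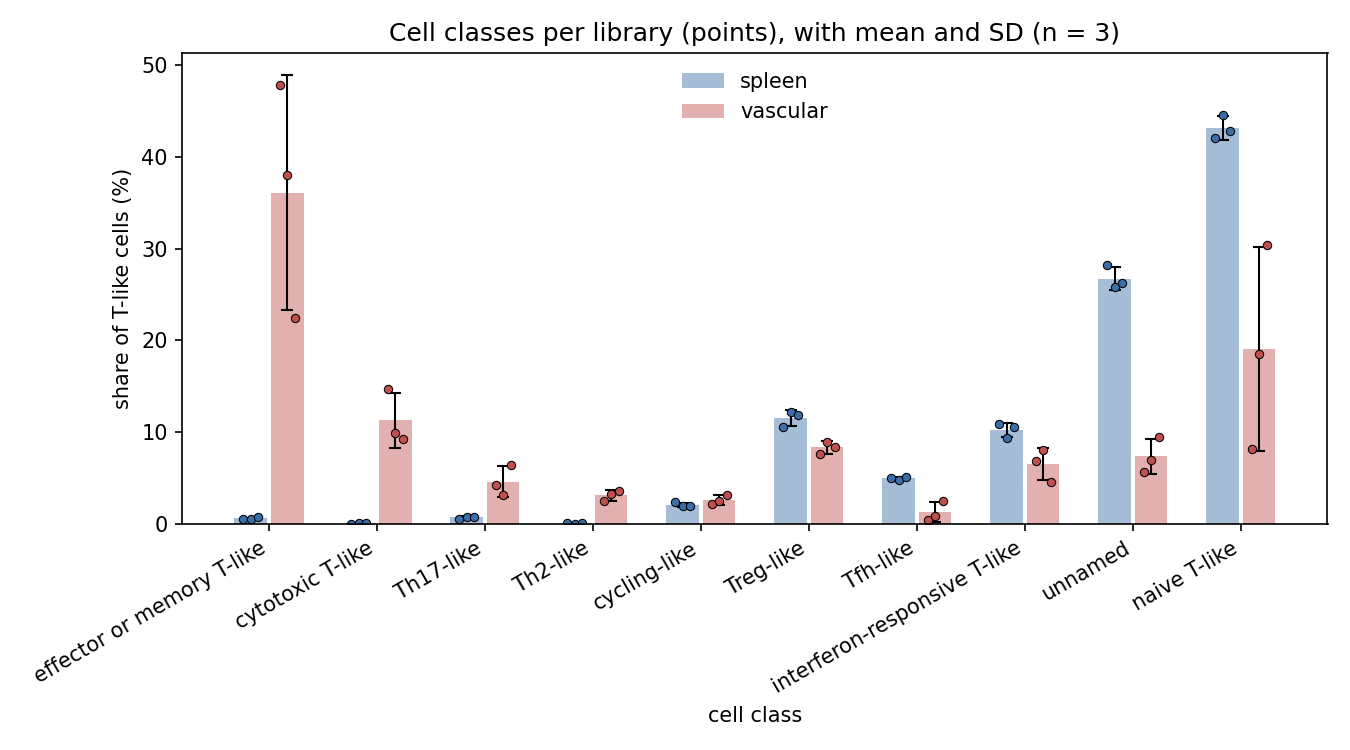
Share of T-like cells (%, vertical axis) in each cell class, spleen in blue and vascular tissue in red, with a point per library, bars at the mean and error bars of 1 SD (n = 3). Effector-or-memory-T-like cells lie at 0.578% in spleen and 36.1% in vascular tissue, naive-T-like cells at 43.2% and 19.0%.

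At an equal depth of 1000 UMIs per cell, more vascular than spleen T-like cells held a UMI of the inflammatory cytokines Ifng and Tnf. Ifng, made by Th1 and cytotoxic cells, was seen in 2.56% ± 0.0972 of spleen and 14.0% ± 4.95 of vascular cells (SD, n = 3), and Tnf in 2.14% and 8.24% ± 0.823. Il17a, the cytokine of Th17 cells, was seen in 0.0645% and 2.09% ± 1.09, and Csf2 in 0.132% and 0.593%. Areg, a growth factor of tissue repair, was seen in 1.33% ± 0.321 and 8.05% ± 1.42, and the granzyme gene Gzmb in 1.47% and 5.04% ± 2.13. Cd4 was seen in 15.5% ± 0.642 and 19.6% ± 1.21, whereas Il4 went the other way, at 0.647% ± 0.264 and 0.202% ± 0.0814. These 8 of the 11 planned genes showed no overlap of libraries (exact p = 0.1, adjusted p = 0.138). Foxp3, the master transcription factor of Treg cells, was seen in 3.72% and 3.76% (exact p = 1), Il10 in 0.441% and 0.477% (exact p = 0.8) and Il21 in 0.348% and 0.236% (exact p = 0.5).

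Chosen after the values were seen, Cd44 was found in 3.61% of spleen and 11.4% ± 1.17 of vascular cells, and Cd69 in 26.0% and 28.8% (exact p = 0.6). Without thinning, Ifng was seen in 7.92% and 28.6%, Il17a in 0.180% and 2.99%, Tnf in 9.60% and 25.4% and Areg in 3.57% and 14.8%. Il4 was seen in 2.31% and 0.653%, Foxp3 in 9.58% and 9.25% and Cd4 in 56.0% and 62.8%. The mean of the library medians was 5213 UMIs in spleen and 4543 in vascular T-like cells. No cell was left out by the thinning. The dendritic cell-like cells, with a median of 8187 UMIs before thinning, served as a background. At the same depth Ifng was seen in 0.0564%, Tnf in 5.32%, Areg in 4.62%, Gzmb in 0.165% and Foxp3 in 0.311% of the vascular ones, and none of the 1159 vascular cells held Il17a, Il4, Il10, Il21 or Csf2. Tnf and Areg were seen in 0.833% and 1.28% of the spleen ones, without overlap of libraries (exact p = 0.1 for both). Unthinned, Tnf was seen in 4.81% and 23.3% and Areg in 6.51% and 16.5%. At 2000 UMIs the Areg libraries of these cells did not overlap (2.53% and 6.40%, exact p = 0.1), but those of Tnf did (1.67% and 7.59%, exact p = 0.2). Higher Areg and, less firmly, Tnf were thus not particular to T-like cells. Dendritic cell-like cells held too little Ifng in either tissue to tell whether its rise was. Fewer dendritic cell-like cells came from spleen, with 155 in all. Cd4 was seen in 16.8% of them in spleen and 20.5% in vascular tissue, and it is expressed by this type of cell in mice.

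Over all T-like cells, 4890 of 12082 genes passed the test, 2708 higher and 2182 lower in vascular tissue. These sums pool classes whose shares differed between the tissues. They do not separate a change in the mix of classes from a change within a class. The inducible heat shock protein 70 genes had the largest rises of the named genes. Hspa1a went from 8.14 ± 1.43 to 1682 ± 81.8 CPM (SD, n = 3), a log2 difference of 7.72 ± 0.16 (SE, adjusted p = 4.5e-08), and Hspa1b from 3.27 ± 0.571 to 506 ± 55.9 CPM (7.31 ± 0.17, adjusted p = 5.9e-08). Il17a rose from 2.68 ± 2.57 to 130 ± 90.2 CPM (5.41 ± 0.67, adjusted p = 0.00041), and Areg from 17.4 ± 3.55 to 225 ± 20.4 CPM (3.71 ± 0.15, adjusted p = 2.2e-06). Cdkn1a, an inhibitor of the cell cycle, rose by 4.23 ± 0.30, the AP-1 gene Fosl2 by 4.0 ± 0.32, Crem, a transcription factor of cAMP signalling, by 3.94 ± 0.22, and Ctla2a, a cysteine protease inhibitor, by 3.44 ± 0.16.

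Of the genes ranked by the fixed rule, Dtx1 and Igfbp4 fell furthest. Dtx1, an E3 ligase of the Notch pathway, fell from 138 ± 18.2 to 29.1 ± 19.3 CPM (-2.25 ± 0.42, adjusted p = 0.0030), and Igfbp4 from 647 ± 55.1 to 179 ± 80.1 CPM (-1.86 ± 0.28, adjusted p = 0.0012). Pdlim4 (-1.80 ± 0.39), Dapl1 (-1.77 ± 0.43), Fam101b (-1.73 ± 0.28), Ly6c1 (-1.65 ± 0.34), Nsg2 (-1.60 ± 0.30) and Actn1 (-1.50 ± 0.28) fell as well, with adjusted p between 0.0015 and 0.011. Cd44, a marker of antigen-experienced cells, rose by 1.63 ± 0.10 (adjusted p = 1.6e-05) and Ifng by 2.71 ± 0.23, from 35.5 ± 2.45 to 233 ± 80.9 CPM (adjusted p = 6.0e-05). Cd4 was 0.36 ± 0.08 higher (adjusted p = 0.0074, or 0.059 without spleen library 2), and Cd8a went from 0.900 to 4.17 CPM (adjusted p = 0.0027). Foxp3 (0.22 ± 0.14, adjusted p = 0.233), Cd69 (0.34 ± 0.20, adjusted p = 0.199) and Il10 (0.27 ± 0.28, adjusted p = 0.459) did not pass. Cd3e lay at 0.07 ± 0.09 (adjusted p = 0.586), and at -0.0120 without spleen library 1.

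Hspa1a (ENSMUSG00000091971) lies on chromosome 17 at 34969190 to 34972156 and Hspa1b (ENSMUSG00000090877) beside it at 34956436 to 34959238, both on the minus strand. Il17a (ENSMUSG00000025929) lies on chromosome 1 at 20730905 to 20734496, Areg (ENSMUSG00000029378) on chromosome 5 at 91139599 to 91148432, Dtx1 (ENSMUSG00000029603) on chromosome 5 at 120680202 to 120711927 and Igfbp4 (ENSMUSG00000017493) on chromosome 11 at 99041244 to 99054392. These are whole protein-coding genes in mm10, since the counts sum over a gene's exons. The tissues did not overlap in 6441 genes, 53.3% of those tested, where chance gives 10%. Without spleen library 2, 3237 genes passed.

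**Figure D2:**
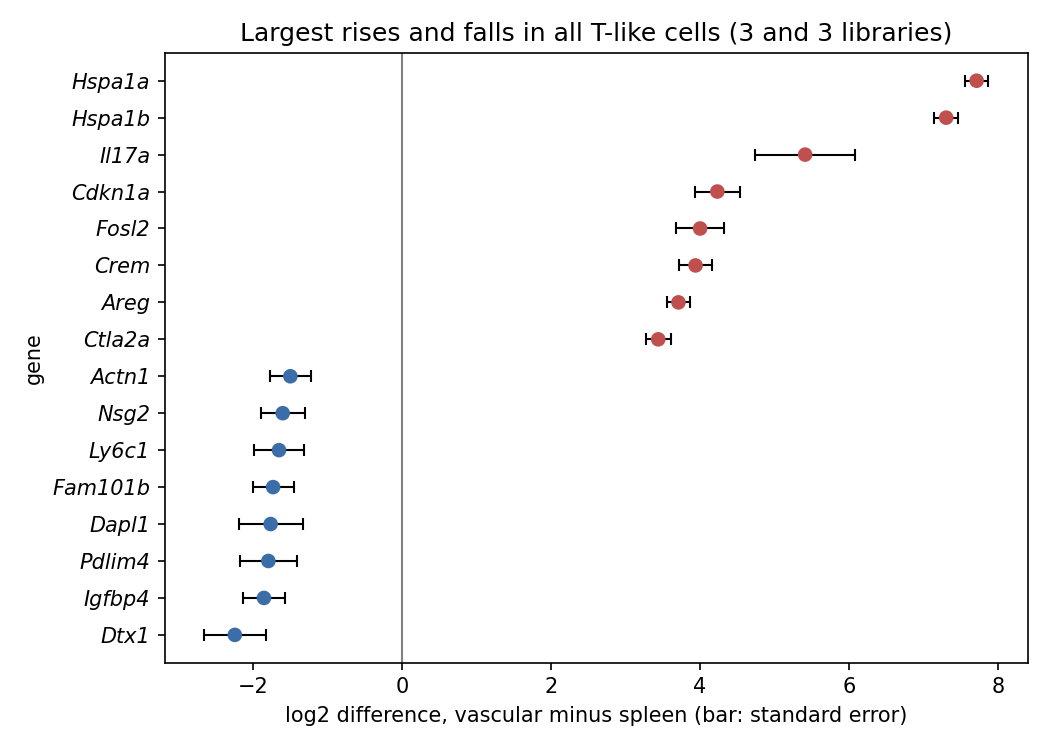
Log2 difference, vascular minus spleen, over all T-like cells (horizontal axis) of the 8 genes with the largest rise and the 8 with the largest fall under the naming rule, with bars of 1 SE (3 and 3 libraries). Hspa1a lies at 7.72 and Dtx1 at -2.25.

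Most genes on the lists of naive, resident and recently stimulated T cells passed. Of 19 measured genes of naive and recirculating cells, 17 fell and 2 rose (19 adjusted over the list alone; camera adjusted p = 1.7e-05, and adjusted p = 0.284 with an estimated correlation). Cd27 (-0.81) and the transcription factor Foxp1 (-0.69) fell, and Il7r, the receptor of the survival cytokine IL-7, rose (0.62). Of 14 tissue residency genes, 13 rose (13 adjusted over the list alone; adjusted p = 3.3e-08, and adjusted p = 0.164 with an estimated correlation), among them Rgs1, a brake on chemokine signalling, from 177 to 1073 CPM. Of 20 immediate early genes, 18 rose (18 adjusted over the list alone; adjusted p = 8.4e-09, and adjusted p = 0.208 with an estimated correlation), such as Ier3 (2.48) and Btg2 (1.76). Of 12 heat shock genes, 11 rose (12 adjusted over the list alone; adjusted p = 5.6e-08, and adjusted p = 0.164 with an estimated correlation). Of 22 T cell activation genes, 19 rose and 1 fell (20 adjusted over the list alone; adjusted p = 3.4e-07, and adjusted p = 0.208 with an estimated correlation), with Tnfrsf4, the costimulatory receptor OX40, going from 115 to 405 CPM. The gene that fell, Myc (-0.44 ± 0.13), had an adjusted p of 0.0854, 0.105, 0.0914 and 0.0895 without spleen library 2 or 3 or vascular library 1 or 2.

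Genes of the Th1, Th17, Th2, Treg and cytotoxicity lists also rose in large part in these pooled sums, whereas Tfh genes were mixed. All 18 Th1 genes rose (18 adjusted over the list alone; adjusted p = 6.6e-09, and adjusted p = 0.257 with an estimated correlation), among them Tnf (2.06) and the cytokine receptor gene Il18r1 (2.11). Of 16 Th17 genes, 15 rose (16 adjusted over the list alone; adjusted p = 1.2e-08, and adjusted p = 0.148 with an estimated correlation), with the nuclear receptor gene Rora at 2.99. Of 10 Th2 genes, 6 rose (8 adjusted over the list alone; adjusted p = 0.00029, and adjusted p = 0.164 with an estimated correlation), with the chemokine receptor gene Ccr8 going from 9.95 to 95.2 CPM. Of 14 Treg core genes, 9 rose and 3 fell (13 adjusted over the list alone; adjusted p = 0.0060, and adjusted p = 0.257 with an estimated correlation), and Izumo1r, the folate receptor 4 of Treg cells, was among those that fell (-1.17). Of 20 tissue Treg genes, 19 rose (19 adjusted over the list alone; adjusted p = 2.6e-11, and adjusted p = 0.148 with an estimated correlation), among them Fgl2 (3.45). Of 17 cytotoxicity genes, 13 rose and 2 fell (15 adjusted over the list alone; adjusted p = 0.00021, and adjusted p = 0.283 with an estimated correlation), with Klrk1, the receptor NKG2D, at 2.72 and the transcription factor Eomes at -1.11.

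Of 24 migration and adhesion genes, 20 rose (22 adjusted over the list alone; adjusted p = 5.8e-09, and adjusted p = 0.208 with an estimated correlation), Adam8 by 3.28. Of 20 cytokine genes, 13 rose and 1, Ltb (-0.54), fell (15 adjusted over the list alone; adjusted p = 0.00019, and adjusted p = 0.148 with an estimated correlation). Of 17 genes of glycolysis and hypoxia, 10 rose (10 adjusted over the list alone; adjusted p = 0.0016, and adjusted p = 0.284 with an estimated correlation), such as Hk2 (2.93), which starts glycolysis, and the glucose transporter gene Slc2a3 (1.04). Of 15 apoptosis genes, 8 rose and 1 fell (9 adjusted over the list alone; adjusted p = 0.0076, and adjusted p = 0.284 with an estimated correlation); the survival gene Bcl2a1d went from 43.8 to 428 CPM, while Bcl2 fell (-0.93). Of 12 inhibitory receptor genes, 7 rose and 2 fell (9 adjusted over the list alone; adjusted p = 0.036, and adjusted p = 0.208 with an estimated correlation), with Pdcd1, the receptor PD-1, at 2.18 and Cd160 at -1.52. Without vascular library 3 this list did not pass (adjusted p = 0.113). Of 17 chemokine receptor genes, 9 rose and 5 fell (14 adjusted over the list alone; adjusted p = 0.048, and adjusted p = 0.208 with an estimated correlation), Ccr2 by 2.49 and the follicle homing receptor Cxcr5 to -1.32. Without spleen library 1 or vascular library 1 it did not pass (adjusted p = 0.0934 and 0.0849), nor with the replicate number as a block.

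Of the 22 lists, 17 passed with the preset correlation (16 higher, 1 lower), and none with an estimated one (lowest adjusted p = 0.148, with 6 lists at an unadjusted p under 0.05). The fry test passed 17. The others were mixed or small in size. Of 14 Tfh genes, 4 rose and 7 fell (12 adjusted over the list alone, adjusted p = 0.585). Of 22 type I interferon response genes 4 rose and 5 fell (9 adjusted over the list alone, adjusted p = 0.724), with Isg20 at 0.89 and Slfn5 at -0.70. Of 16 lipid handling genes, 4 rose and 6 fell (10 adjusted over the list alone, adjusted p = 0.524), the fatty acid binding protein gene Fabp5 by 1.48. Of 17 proliferation genes, 5 rose (1 adjusted over the list alone, adjusted p = 0.087), Tyms by 0.61, and the list passed without spleen library 1, vascular library 1 or vascular library 2 (adjusted p = 0.0353, 0.0251 and 0.0354). Of 17 oxidative phosphorylation genes, 4 fell (3 adjusted over the list alone, adjusted p = 0.443), Sdhb to -0.40, and the list passed as lower without spleen library 1 (adjusted p = 0.0329).

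**Figure D3:**
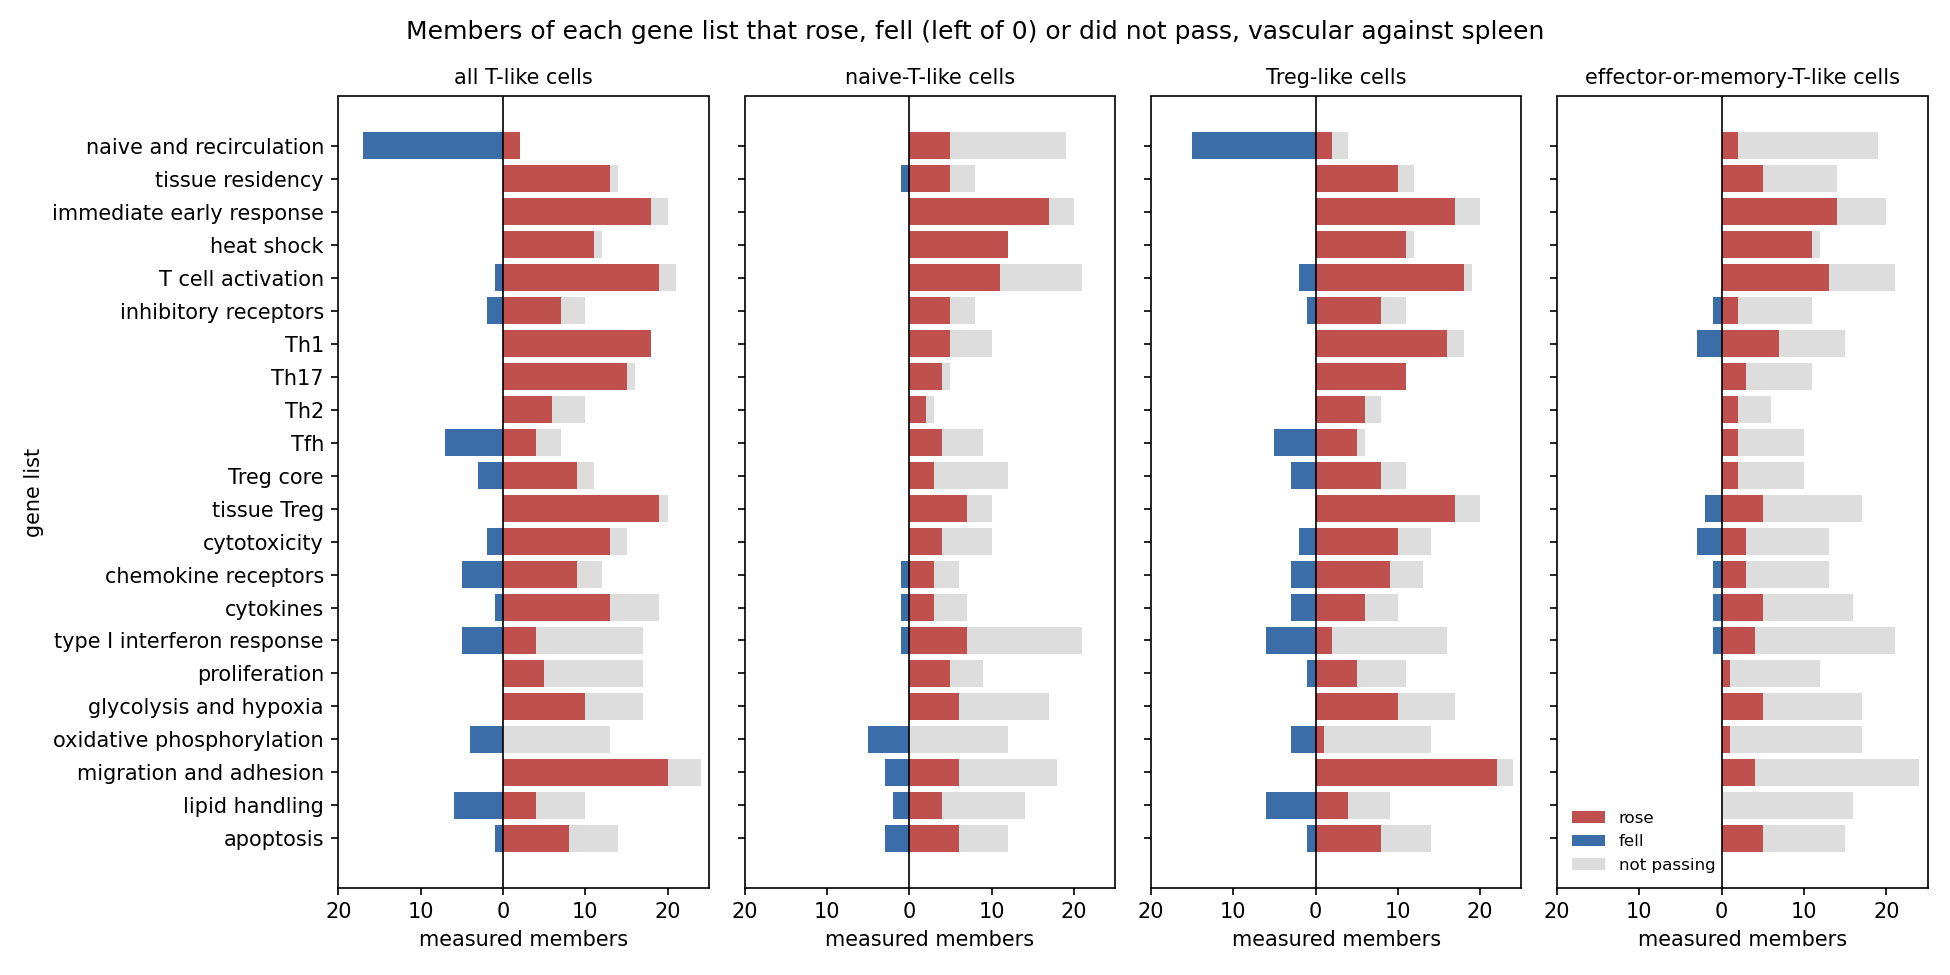
Members of each of the 22 gene lists (vertical axis) that rose (red), fell (blue, left of 0) or did not pass (grey) in 4 sets of cells, as numbers of measured genes (horizontal axis). In all T-like cells 17 of 19 naive and recirculation genes fell, and in naive-T-like cells 5 of 19 rose.

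Markers of other cell types were measured in the same sums. Each gene in brackets is its list's member with the highest vascular level, and of these Bst2, Gsn, Gzma, Cd8b1, Acta2 and Hbb-bs did not pass themselves. Of 13 macrophage or monocyte markers, 7 rose and 1 fell, with Lyz2 going from 1.06 ± 0.591 to 12.5 ± 1.63 CPM and Apoe from 3.80 to 14.2. Its highest member, Ly6c2 at 441 CPM in vascular tissue, is on the Th1 list too. Of 8 dendritic cell markers 6 rose (Bst2, 270 CPM), with 2 of the 8 also on T cell lists, and of 6 fibroblast markers 5 rose (Gsn, 20.4 CPM). Of 5 plasma cell markers 2 rose (Xbp1, 74.3 CPM), of 3 neutrophil markers 2 rose (Mmp9, 8.88 CPM), and of 9 NK or ILC markers 2 rose and 2 fell (Gzma, 20.4 CPM). Of 2 CD8 T markers 1 rose (Cd8b1, 18.2 CPM), of 2 smooth muscle markers 1 rose (Acta2, 4.10 CPM), and the only measured gamma delta T marker (Cd163l1, 1.33 CPM) and platelet marker (Pf4, 0.630 CPM) rose. Of 5 B cell markers 1 rose and 3 fell (H2-Aa, 18.3 CPM), of 2 endothelial markers 1 fell (Pecam1, 32 CPM), and none of 5 erythroid markers passed (Hbb-bs, 68.5 CPM). No mast cell or basophil and no adipocyte marker passed the count filter. In a T-like cluster led by H2-Aa, Apoe and Lyz2 lay 0.266% of spleen and 1.59% of vascular T-like cells, and without it 4858 genes passed.

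Naive-T-like cells of the vascular tissue carried more heat shock and immediate early RNA than those of the spleen at the preset correlation. Neither list passed with an estimated correlation (adjusted p = 0.163 for both). Hspa1a went from 2.82 to 1268 ± 753 CPM (8.83 ± 0.50, adjusted p = 4.3e-06) and Hspa1b from 1.41 to 409 ± 212 CPM (8.32 ± 0.47, adjusted p = 4.3e-06). Crem rose by 3.79 ± 0.32, Fosl2 by 3.38 ± 0.30 and Phlda1, a gene induced by T cell receptor signals, by 3.18 ± 0.22, from 13.1 to 115 CPM (adjusted p = 1.4e-05). The falls were smaller among the genes ranked, which by rule exclude haemoglobin genes. Polr2j, a subunit of RNA polymerase II, fell to -0.96 ± 0.13, Abhd8 to -0.93 ± 0.12, Cnp to -0.90 ± 0.18 and Psmc1, a proteasome subunit, to -0.87 ± 0.11. Nrros fell to -1.02 ± 0.24 (adjusted p = 0.012, or 0.063 without vascular library 2). Cd44 lay at 0.52 ± 0.18 (adjusted p = 0.060) and Cd4 at 0.24 ± 0.10 (adjusted p = 0.092). Cd3e lay at -0.05 ± 0.11 (adjusted p = 0.781, with a log2 difference of 0.0170 without spleen library 3) and Foxp3 at 0.37 ± 0.36 (adjusted p = 0.493). Cd69 lay at -0.43 ± 0.12 (adjusted p = 0.029), and did not pass without spleen library 2 or 3 or vascular library 2 or 3 (adjusted p = 0.173, 0.0788, 0.105 and 0.0729).

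In all, 2095 of 9536 genes passed in naive-T-like cells, 1246 higher and 849 lower, and 38.8% showed no overlap where chance gives 10%. The count was 988, 1095 and 1188 without spleen library 2, spleen library 3 or vascular library 2, and 1321 over cells with a UMI of Cd4 and none of Cd8a or Cd8b1. Different clusters held most of the class in the tissues. In spleen these were a cluster led by Igfbp4, Pdlim4 and Dapl1 (33.4% of T-like cells, 1.66% in vascular tissue) and one led by Myo6 and Atp1b1 (9.40% and 0.852%). In vascular tissue they were a cluster with Tubb2a, Ifngr2, Dusp10 and Ccr7 (0.107% and 10.3%) and one led by Hspa1b and Hspa1a (0.224% and 6.17% ± 7.34), most of whose cells came from vascular library 3. Without the last of these, 2820 genes passed.

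List members named for the classes were chosen after their values had been seen. In naive-T-like cells all 12 heat shock genes rose (12 adjusted over the list alone; adjusted p = 4.3e-12, and adjusted p = 0.163 with an estimated correlation) and 17 of 20 immediate early genes rose (17 adjusted over the list alone; adjusted p = 4.3e-12, and adjusted p = 0.163 with an estimated correlation), among them Gadd45b (2.39) and Egr1 (1.54). Of 21 activation genes 11 rose (14 adjusted over the list alone; adjusted p = 2.7e-05, and adjusted p = 0.163 with an estimated correlation), such as Nr4a2, from 6.94 to 45.1 CPM, and Icos, from 49.7 to 125 CPM. Of 10 tissue Treg genes 7 rose (8 adjusted over the list alone; adjusted p = 5.4e-05, and adjusted p = 0.163 with an estimated correlation), and of 10 Th1 genes 5 rose, Tnf from 8.25 to 28.5 CPM (5 adjusted over the list alone; adjusted p = 0.0026, and adjusted p = 0.205 with an estimated correlation). Of 19 naive and recirculation genes 5 rose and none fell (5 adjusted over the list alone, adjusted p = 0.504), Ccr7, which guides cells into lymph nodes, from 697 to 1305 CPM. Of 9 residency genes 5 rose and 1 fell (6 adjusted over the list alone; adjusted p = 0.0090, and adjusted p = 0.163 with an estimated correlation), Rgs1 by 1.25. Lyz2 went from 0.632 to 3.04 CPM and Cd74 from 10.7 to 28.5 CPM in the same cells. The erythroid marker Hbb-bs fell from 544 ± 476 to 0.287 ± 0.0867 CPM there (-10.95 ± 0.92, adjusted p = 2.7e-05), and Hba-a1 from 124 ± 156 to 0 CPM (adjusted p = 0.0046).

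Of the other lists in naive-T-like cells, those of inhibitory receptors (5 of 8 rose, 6 adjusted over the list alone), Th17 (4 of 5, 4 adjusted over the list alone) and Tfh genes (4 of 9, 4 adjusted over the list alone) passed with adjusted p = 0.0092, 0.0090 and 0.0094, and had adjusted p = 0.221, 0.163 and 0.163 with an estimated correlation. Treg core genes (3 of 12 rose) passed at adjusted p = 0.039, and had adjusted p = 0.265 with an estimated correlation. Of 22 type I interferon response genes 7 rose and 1 fell (adjusted p = 0.031, and adjusted p = 0.545 with an estimated correlation), Isg15 from 55.1 to 106 CPM, but the list did not pass without spleen library 2 or vascular library 3 (adjusted p = 0.0614 and 0.460). Cytotoxicity (adjusted p = 0.020, or 0.0645 without vascular library 3) and proliferation (0.015, or 0.0690 without spleen library 1) passed, and had adjusted p = 0.163 and 0.205 with an estimated correlation. Glycolysis and hypoxia passed (0.020, or 0.116 and 0.0694 without spleen library 1 or vascular library 1), as did Th2 genes (0.036, or 0.174 and 0.0876 without spleen library 1 or vascular library 2). They had adjusted p = 0.265 and 0.205 with an estimated correlation. Cytokines passed (0.0497, or 0.101, 0.0735 and 0.0595 without spleen library 1, vascular library 2 or vascular library 3), with adjusted p = 0.205 with an estimated correlation. Chemokine receptors did not pass (adjusted p = 0.052), although they did without any 1 library (adjusted p from 0.00900 to 0.0367) and with the replicate number as a block. Oxidative phosphorylation genes, of which 5 of 17 fell, did not pass (adjusted p = 0.108) except without spleen library 1 (0.0148), and migration and adhesion genes had a median of -0.04 but a test direction upwards (adjusted p = 0.361). Lipid handling (adjusted p = 0.354) and apoptosis genes (adjusted p = 0.097) did not pass either. In all 16 lists passed, each of them higher, and none with an estimated correlation (5 at an unadjusted p under 0.05, and 17 by fry).

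In Treg-like cells the tissue Treg list was higher in vascular tissue at the preset correlation, with adjusted p = 0.0555 with an estimated one. At the preset correlation the list also passed in all T-like and naive-T-like cells. Of the genes named below for Treg-like cells, Klrg1, Il1rl1, Gpr83, Foxp3, Lrrc32, Tnfrsf4 and Tnfrsf18 were also on the marker list that named Treg clusters. Summed over Treg-like cells, Areg rose from 119 to 1385 CPM (3.58 ± 0.14, adjusted p = 3.1e-09) and Il1rl1, the receptor of the alarmin IL-33, from 4.41 to 113 CPM (4.47 ± 0.23, adjusted p = 2.3e-08). Klrg1, an inhibitory receptor of differentiated cells, rose from 95.6 to 488 CPM and Pdcd1 from 50.6 to 448 CPM. Tff1, a trefoil peptide of mucosal epithelium, had 2 UMIs in the spleen cells and 1180 in the vascular cells, a ratio of 844 with a 95% counting interval of 233 to 6981 (adjusted p = 5.8e-09). Dgat2, the last enzyme of triglyceride synthesis, rose from 4.61 to 166 CPM (5.10 ± 0.19, adjusted p = 1.2e-09). Gpr83, a receptor of resting Treg cells, fell from 54.8 to 9.26 CPM (-2.58 ± 0.26, adjusted p = 8.3e-06).

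Hspa1b (7.63 ± 0.23) and Hspa1a (7.22 ± 0.16) rose in Treg-like cells too, as did Igfbp7 (6.43 ± 1.43, adjusted p = 0.0038), mostly in vascular library 1 with 279 CPM against 13.9 and 10.2 CPM in the others. Dtx1 (-3.53 ± 0.27), Ly6c1 (-2.69 ± 0.18), Igfbp4 (-2.33 ± 0.30) and Nsg2 (-2.11 ± 0.18) fell with adjusted p between 2.3e-07 and 7.0e-05. Cd44 rose by 1.75 ± 0.10, Ifng by 1.98 ± 0.29, and Il17a had 1 spleen UMI and a ratio of 484 with an interval of 86.2 to 19165. Foxp3 itself lay at 387 and 430 CPM (0.14 ± 0.10, adjusted p = 0.270), and did not pass. Neither did Il10 (-0.11 ± 0.34, adjusted p = 0.832, but 0.11 and 0.21 without spleen library 1 or vascular library 3), Cd69 (0.14 ± 0.12, adjusted p = 0.404) and Cd3e (0.04 ± 0.08, adjusted p = 0.763, and -0.00761 and -0.0165 without spleen library 1 or 2). Cd4 rose by 0.39 ± 0.09 (adjusted p = 0.0050, or 0.0585 without spleen library 2). Markers of macrophages were higher in the same cells: Lyz2 went from 0.535 to 38.1 ± 6.75 CPM and Apoe from 3.61 to 44.9 CPM. H2-Aa, an MHC class II gene that B cells share with macrophages and dendritic cells, went from 4.88 to 54.1 CPM. Of 9313 genes, 3218 passed, 1813 higher and 1405 lower, and 45.4% showed no overlap where chance gives 10%. With equal cell numbers per library 1874 passed, and over cells with a UMI of Cd4 and none of Cd8a or Cd8b1 2061. Most spleen Treg-like cells lay in a cluster led by Lrrc32, Gpr83 and Foxp3 (8.46% of T-like cells, 0.758% in vascular tissue) and most vascular ones in a cluster with Cxcl2, Klrg1, Dgat2 and Areg (0.116% and 6.95%). Another cluster of the class (2.98% and 0.612%) had an Areg UMI in 35.5% and a Klrg1 UMI in 28.2% of cells. These shares were 10.5% and 1.20% in the main spleen cluster and 72.6% and 60.6% in the main vascular one. The sums thus do not separate a change in the mix of Treg-like clusters from a change within them.

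Of 20 tissue Treg genes in these cells 17 rose (18 adjusted over the list alone; adjusted p = 2.4e-11, and adjusted p = 0.0555 with an estimated correlation), Fgl2 from 19.1 to 171 CPM. Of 14 Treg core genes 8 rose and 3 fell (11 adjusted over the list alone), which did not pass as a list (adjusted p = 0.058), though it did without spleen library 2, spleen library 3 or vascular library 2 (adjusted p = 0.0449, 0.0499 and 0.0366). Tnfrsf4 (1.36) and Tnfrsf18, the receptor GITR (1.20), rose and Izumo1r fell from 949 to 409 CPM. Of 24 migration and adhesion genes 22 rose (22 adjusted over the list alone; adjusted p = 3.0e-10, and adjusted p = 0.0555 with an estimated correlation). All 11 Th17 genes rose (11 adjusted over the list alone; adjusted p = 7.4e-08, and adjusted p = 0.0555 with an estimated correlation), Rora from 57.0 to 463 CPM. Of 18 Th1 genes 16 rose (17 adjusted over the list alone; adjusted p = 6.0e-09, and adjusted p = 0.124 with an estimated correlation), and of 12 residency genes 10 rose (11 adjusted over the list alone; adjusted p = 1.6e-07, and adjusted p = 0.0555 with an estimated correlation), Cxcr6 from 7.55 to 159 CPM. Of 19 naive and recirculation genes 15 fell and 2 rose (17 adjusted over the list alone; adjusted p = 6.2e-06, and adjusted p = 0.243 with an estimated correlation), Klf3 to -1.62.

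Of 21 activation genes in Treg-like cells 18 rose (adjusted p = 7.4e-08), of 20 immediate early genes 17 (adjusted p = 1.6e-07), of 12 heat shock genes 11 (adjusted p = 2.3e-07) and of 8 Th2 genes 6 (adjusted p = 0.00037). With an estimated correlation these 4 had adjusted p = 0.124, 0.139, 0.114 and 0.114. Genes of inhibitory receptors (8 of 12 rose, adjusted p = 0.0046), cytotoxicity (10 of 16, adjusted p = 0.0033), glycolysis and hypoxia (10 of 17, adjusted p = 0.0013), apoptosis (8 of 15, adjusted p = 0.013) and chemokine receptors (9 of 16, adjusted p = 0.015) passed too, and had adjusted p = 0.124, 0.159, 0.249, 0.138 and 0.124 with an estimated correlation. Chemokine receptors did not pass without vascular library 3 (adjusted p = 0.0529). Egln3, a sensor of oxygen, rose from 12.5 to 57.0 CPM, Plin2, a coat protein of lipid droplets, from 17.5 to 98.5 CPM, and Bcl2 fell from 144 to 45.3 CPM. In all 15 of 22 lists passed, and none with an estimated correlation (7 at an unadjusted p under 0.05, and 19 by fry). Cytokines did not pass (adjusted p = 0.153), except without spleen library 2, spleen library 3 or vascular library 1 (0.0292, 0.0498 and 0.0148). Type I interferon response (0.275) and proliferation genes (0.074) did not pass either, except the former, as lower, without spleen library 2 (0.0253) and the latter without vascular library 2 (0.0207). Tfh (adjusted p = 0.822), oxidative phosphorylation (0.622) and lipid handling genes (0.733) did not pass.

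Cells named effector-or-memory-T-like were scarce in the spleen, with 43 and 57 cells in libraries 2 and 3 and 11 in library 1, which was left out. Spleen cells of the unnamed clusters were not part of this class. All spleen cells of the class lay in a cluster led by Hspa1a, Ifng and Hspa1b (0.578% of T-like cells, 20.8% ± 7.21 in vascular tissue). The other cluster of the class, led by Serpinb9 and Bcl2a1d, took 15.2% ± 7.72 of vascular T-like cells and held no spleen cell. This allows up to 0.142% in spleen library 1, the smallest, and less in the others. Heat shock and immediate early genes were higher in the vascular cells of the class at the preset correlation. Neither list passed with an estimated correlation (adjusted p = 0.534 for both). Hspa1a lay at 7.45 without the cluster that held no spleen cell, a test chosen after the data had been seen. Hspa1a went from 20.4 to 2454 CPM (6.90 ± 0.20, adjusted p = 7.0e-11), the co-chaperone gene Dnajb1 from 173 to 1463 CPM and Nr4a1, a nuclear receptor induced by T cell receptor signals, from 140 to 1027 CPM (2.91 ± 0.20). Ifng rose from 278 to 479 CPM (0.75 ± 0.16, adjusted p = 0.011, or 0.0912 without spleen library 2). Dtx1 fell from 274 to 11.5 CPM (-4.67 ± 0.27, adjusted p = 2.6e-07), the surface receptor gene Cd7 from 178 to 21.9 CPM (-3.05 ± 0.36, adjusted p = 0.00011) and the chemokine gene Ccl5 from 6843 to 2454 CPM (-1.48 ± 0.12, adjusted p = 3.1e-06).

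Hspa1b had 2 spleen UMIs in this class and a ratio of 152 with an interval of 42.1 to 1256, and Nr4a3 1 spleen UMI and a ratio of 45.0 with an interval of 8.07 to 1779. Klf4, with no spleen UMI, was at least 8.58-fold higher (adjusted p = 0.043), and Areg, with 1 spleen UMI, had a ratio of 37.8 with an interval of 6.77 to 1492 (adjusted p = 0.0039). Neither Klf4 nor Areg passed without spleen library 2 (adjusted p = 0.295 and 0.116) or 3 (0.443 and 0.146), or without the cluster that held no spleen cell (0.0729 and 0.0623). Ifitm1 fell by 2.99 ± 0.49 on the log2 scale, but had an adjusted p of 0.370 without spleen library 2 and lay 2.57 higher with the finer clustering. Fam101b (-2.08 ± 0.30) did not pass without spleen library 3 (adjusted p = 0.158), nor Serpina3g (-1.96 ± 0.31) without spleen library 2 (adjusted p = 0.157). Cd69 lay 0.80 ± 0.17 higher (adjusted p = 0.011, or 0.104 and 0.269 without spleen library 2 or 3). Cd4 (0.24 ± 0.12, adjusted p = 0.359, but -0.0314 with the finer clustering), Cd44 (0.49 ± 0.19, adjusted p = 0.196) and Cd3e (-0.01 ± 0.09, adjusted p = 0.980) did not pass. Of 9946 genes, 547 passed, 431 higher and 116 lower, and 50.2% showed no overlap where chance gives 20% for 2 libraries against 3. The median over all genes lay at 0.10 here and at 0.05 with DESeq2, which called 360 higher and 210 lower and gave no adjusted p to 5208 genes. Without the cluster that held no spleen cell 237 genes passed, 175 higher and 62 lower. Without spleen library 2 or 3 the count was 220 and 200, and it was 282 with equal cell numbers per library, 835 without the filter on low counts, and 927 with a coarser clustering. The finer clustering gave 3248, with 44, 168 and 222 spleen cells in 3 libraries.

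In this class 11 of 12 heat shock genes rose (11 adjusted over the list alone; adjusted p = 5.8e-06, and adjusted p = 0.534 with an estimated correlation) and 14 of 20 immediate early genes rose (16 adjusted over the list alone; adjusted p = 8.0e-06, or 0.0502 without spleen library 3, and adjusted p = 0.534 with an estimated correlation). Of 21 activation genes 13 rose (19 adjusted over the list alone; adjusted p = 7.7e-05, and adjusted p = 0.534 with an estimated correlation), Icos from 286 to 914 CPM and Nfkbid from 68.0 to 278 CPM. Without the cluster that held no spleen cell these 3 lists passed too (adjusted p = 5.7e-08 for the first 2 and 0.0020 for activation genes), with Icos at 1.08 in place of 1.67. Of 14 residency genes 5 rose (7 adjusted over the list alone; adjusted p = 0.047, and adjusted p = 0.534 with an estimated correlation), Crem by 3.53 and Rgs2 by 2.52, and this list did not pass without spleen library 2, spleen library 3 or vascular library 3 (adjusted p = 0.182, 0.267 and 0.0597), or without the cluster that held no spleen cell (0.112), where Crem lay at 2.43. The residency list did not pass with the replicate number as a block either. The other 18 lists did not pass, with adjusted p from 0.102 for Th17 genes to 0.872 for cytotoxicity. Exceptions were apoptosis without vascular library 1 (adjusted p = 0.0462), type I interferon response genes without the cluster that held no spleen cell (0.0172) and Th17 genes with the replicate number as a block. Of 18 Th1 genes 7 rose and 3 fell (11 adjusted over the list alone, adjusted p = 0.641), Ly6c2 from 245 to 830 CPM. Of 15 apoptosis genes 5 rose (8 adjusted over the list alone, adjusted p = 0.173), Bcl2a1d from 150 to 731 CPM (2.31, or 1.18 without the cluster that held no spleen cell), and of 17 genes of glycolysis and hypoxia 5 rose (5 adjusted over the list alone, adjusted p = 0.256), among them Hif1a, the transcription factor of the hypoxia response, from 146 to 450 CPM.

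Hspa1a rose in every class with a fit. Besides the values above it lay 8.38 ± 0.19 higher in interferon-responsive, 7.87 ± 0.21 in Tfh-like, 5.88 ± 0.35 in cycling-like and 5.84 ± 0.24 in Th17-like cells, the last from 2 spleen libraries. In the non-T classes it lay 5.33 ± 0.26 higher in dendritic cell-like cells. In B cell-like cells it had 3 spleen UMIs and a ratio of 448 with an interval of 153 to 2177.

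**Figure D4:**
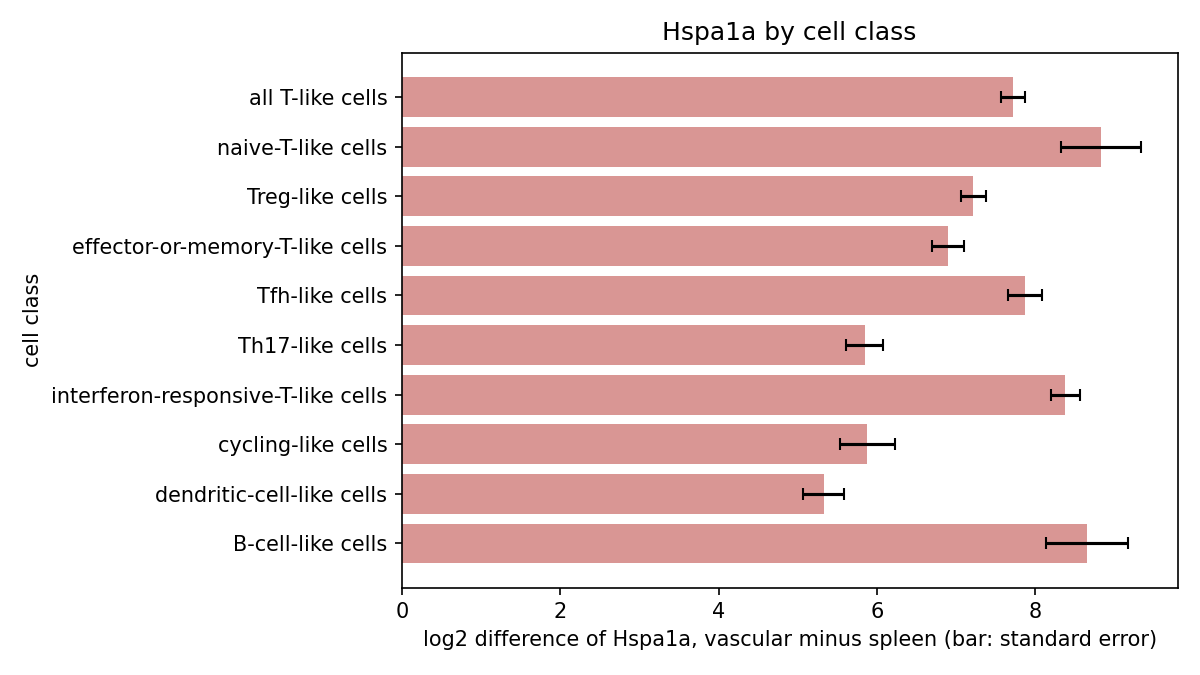
Log2 difference of Hspa1a, vascular minus spleen (horizontal axis), in each cell class with a fit, with bars from 0 and error bars of 1 SE (3 and 3 libraries, or 2 spleen and 3 vascular for effector-or-memory-T-like and Th17-like cells). The values run from 5.33 in dendritic cell-like to 8.83 in naive-T-like cells, and that of B cell-like cells rests on 3 spleen UMIs and depends on the prior count of the fit.

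The tissue difference itself differed between Treg-like and effector-or-memory-T-like cells in 358 of 10341 genes, 116 in the positive and 242 in the negative direction. Cxcr6, a chemokine receptor of tissue-resident cells, went from 8.78 to 155 CPM in Treg-like cells and from 491 to 625 CPM in effector-or-memory-T-like cells, a difference of 3.77 ± 0.19 between the log2 differences (adjusted p = 1.3e-12, and 2.27 with the finer clustering). Ctla2a went from 20.4 to 538 CPM and from 182 to 430 CPM (3.50 ± 0.22, adjusted p = 1.7e-10), whereas Ssbp2 went from 52.9 to 29.8 CPM in Treg-like and from 26.7 to 66.0 CPM in effector-or-memory-T-like cells (-2.13 ± 0.33, adjusted p = 0.00011). Between naive-T-like and effector-or-memory-T-like cells 108 of 10475 genes differed, 36 in the positive and 72 in the negative direction. Dtx1 went from 127 to 73.0 CPM in naive-T-like and from 242 to 10.1 CPM in effector-or-memory-T-like cells (3.76 ± 0.20, adjusted p = 1.3e-15), and Ccl5 from 4.67 to 20.5 CPM and from 6037 to 2167 CPM (3.59 ± 0.24, adjusted p = 8.6e-13). Both tests rest on the same 2 spleen and 3 vascular libraries, and for effector-or-memory-T-like cells they compare spleen cells of 1 cluster with vascular cells of 2. Without the cluster that held no spleen cell 424 and 122 genes differed, and Cxcr6, Ctla2a, Ssbp2, Dtx1 and Ccl5 passed. The median over all genes lay at -0.15 in the Treg-like and -0.13 in the naive-T-like comparison. With RLE scaling alone it was -0.0374 and -0.0516, with 147 positive and 173 negative genes and with 39 and 43. With DESeq2 it was 0.000730 and -0.0172, with 196 and 133 and with 29 and 27, and 7311 genes of the naive-T-like comparison got no adjusted p from it. Without spleen library 2 or 3 the counts were 203 and 178 for the Treg-like and 21 and 20 for the naive-T-like comparison, which was 180 without vascular library 3. With the finer clustering they were 2153 and 1254, from 6 libraries and more spleen effector-or-memory-T-like cells.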

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

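The classes other than T cells were described only after they had been seen, while the tests of differences between classes were planned. The difference between vascular tissue and spleen differed between Treg-like and effector-or-memory-T-like cells in 358 genes (edgeR interaction test, 2 spleen and 3 vascular libraries), and 10 were named by the fixed rule, each as the log2 difference in Treg-like cells minus that in effector-or-memory-T-like cells. Cxcr6 (3.77 ± 0.19), Ctla2a (3.50 ± 0.22) and Ssbp2 (-2.13 ± 0.33) passed without any 1 library, as did Ifitm1 (7.46 ± 0.60), whose level was 0.296 and 7.42 CPM in Treg-like and 592 and 73.9 CPM in effector-or-memory-T-like cells, with 3 UMIs in Treg-like spleen cells. With the finer clustering Ifitm1 did not pass (1.84, adjusted p = 0.160). Ifitm2 (3.52 ± 0.38) went from 12.5 to 42.9 CPM and from 560 to 158 CPM, and turned to -1.86 with the finer clustering. Klrk1 (4.09 ± 1.02, -0.89 with the finer clustering) did not pass without spleen library 2 or 3 (adjusted p = 0.398 and 0.261), nor did Nfil3 (-2.82 ± 0.69, adjusted p = 0.243 and 0.0684) and Pdcd1lg2 (-2.26 ± 0.62, adjusted p = 0.116 and 0.589). Id3 (-2.92 ± 0.63, 0.32 with the finer clustering) and Ly6c1 (-2.66 ± 0.38) did not pass without spleen library 3 (adjusted p = 0.475 and 0.0678). Without the effector-or-memory-T-like cluster that held no spleen cell, a test chosen after the data had been seen, Nfil3 and Pdcd1lg2 did not pass (adjusted p = 0.203 and 0.289). Ifitm1, Klrk1, Id3, Nfil3 and Pdcd1lg2 had 2 or 3 UMIs in the spleen cells of 1 class, so their sizes depend on the prior count of the fit.

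Between naive-T-like and effector-or-memory-T-like cells 108 genes differed by the same test. Dtx1 (3.76 ± 0.20) and Ccl5 (3.59 ± 0.24) passed without any 1 library. Ifitm2 (4.16 ± 0.61) did not pass without spleen library 2 (adjusted p = 0.275) and turned to -1.05 with the finer clustering, and Gzmk (3.71 ± 0.93) did not pass without spleen library 2 or 3 or vascular library 2 or 3 (adjusted p = 0.406, 0.251, 0.126 and 0.119). Without spleen library 2 or 3 the other 6 genes did not pass: Ccr2 (3.41 ± 0.65, adjusted p = 0.160 and 0.146), the histone demethylase gene Kdm6b (-2.78 ± 0.52, 0.231 and 0.410), Sik1 (-2.56 ± 0.65, 0.583 and 0.616), Serpinb9 (-2.0 ± 0.39, 0.344 and 0.419), the RNase gene Zc3h12a (-1.91 ± 0.34, 0.199 and 0.177) and Pde4d (-1.85 ± 0.45, 0.463 and 0.617). Without the cluster that held no spleen cell Gzmk, Kdm6b, Sik1, Serpinb9, Zc3h12a and Pde4d did not pass (adjusted p = 0.0712, 0.391, 0.243, 0.761, 0.448 and 0.172). Gzmk had 2 UMIs in naive-T-like and Sik1 3 in effector-or-memory-T-like spleen cells, so their sizes depend on the prior count too. These effector-or-memory-T-like sums hold only 43 and 57 spleen cells, and 44, 168 and 222 with the finer clustering.

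The sort for CD4+ T cells also held 1314 cells like dendritic cells, 155 from spleen and 1159 from vascular tissue, and 350 cells like B cells, counts above the 3 that a count of 0 allows. In dendritic cell-like cells 777 genes passed between the tissues, 471 higher and 306 lower. Bcl2l11, which promotes cell death, rose by 3.91 ± 0.29. Hspa1b (2 spleen UMIs) had a ratio of 101 with a counting interval of 27.9 to 835 and Spsb1 (3 spleen UMIs) one of 29.8 with 10.2 to 145, while the sterol synthesis genes Hmgcs1 (-2.03 ± 0.24) and Fdps (-1.96 ± 0.17) and the cytokine gene Ltb (-2.44 ± 0.20) fell. In B cell-like cells 437 genes passed, 310 higher and 127 lower, with the chemokine gene Cxcl10 rising by 5.75 ± 0.93, mostly in vascular library 1 with 1030 CPM against 90.2 and 233 CPM in the others, and the germinal centre gene Rgs13, with 2 vascular UMIs, at a ratio of 0.0277 with an interval of 0.00331 to 0.102. Siglech, a marker of the dendritic cell-like cells, reached 2.79 CPM in vascular T-like cells.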

How the results depend on the processing

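Leaving out doubted clusters or gene lists was chosen after seeing the data, and all other alternatives were planned. Of the values for whole comparisons (counts of genes and lists, and means), 134 lay within 1.5 times the reported value or within 1 SD and 34 moved further. Of those for single genes 4053 kept direction and side of the threshold, 224 lost and 10 gained a call and 23 turned; for lists these were 683, 75, 40 and 16. Leaving out 1 library gave 3237 to 5842 genes in all T-like, 988 to 2999 in naive-T-like, 2259 to 3581 in Treg-like and 200 to 505 in effector-or-memory-T-like cells, 178 to 387 and 20 to 180 in the comparisons of the latter with Treg-like and naive-T-like cells, and 16 to 18, 14 to 17, 14 to 18 and 2 to 5 gene lists. Spleen library 1 was in the effector-or-memory fits only at resolution 2. DESeq2 gave 4498, 1720, 2210 and 570 genes, and 56 for the naive-T-like comparison, giving no adjusted p to 5208 effector-or-memory genes and 7311 of that comparison. No filter on low counts gave 835 effector-or-memory genes and 541 and 186 for the comparisons, where more genes were tested. Equal cell numbers gave 1874 Treg-like and 282 effector-or-memory genes, and 210 and 48, with fewer cells. Cells with a UMI of Cd4 and none of Cd8a or Cd8b1 gave 1321 naive-T-like, 2061 Treg-like and 66 genes. Resolution 2, with 44, 168 and 222 spleen cells in the effector-or-memory class in place of 43 and 57, gave 3248, 2153 and 1254 and resolution 0.5 927 and 759, and the cause was not tested. Centred clustering left under 20 effector-or-memory cells in every spleen library, so that fit could not be made. Without the effector-or-memory cluster that held no spleen cell 237 genes passed, and the cytotoxicity list turned to lower (adjusted p = 0.659). Without the heat shock and immediate early lists 4836, 2061, 3184 and 532 genes passed. With an estimated correlation 0 lists passed in each of the 4 sets of cells (6, 5, 7 and 0 at an unadjusted p under 0.05), and fry passed 17, 17, 19 and 16.

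The replicate number as a block gave 4735, 2572, 3166 and 561 genes and 16, 17, 15 and 4 lists. It took chemokine receptors in all T-like (adjusted p = 0.0598) and tissue residency in effector-or-memory-T-like cells (0.0573) past 0.05, brought chemokine receptors in naive-T-like (0.0234) and Th17 genes in effector-or-memory-T-like cells (0.0199) under it, and turned Cd3e in the latter to 0.00361. Deviations of libraries with the same number correlated at 0.0448, -0.226 and 0.169 over 8813 genes. Spleen libraries 1 and 2 correlated better with vascular libraries 2 (0.211) and 3 (0.151). These values give no sign of pairing by number, but cannot settle whether equal numbers mark the same animals.

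Values that turned direction were mostly small and not called, and the cause was not tested. Without 1 library Cd3e ran from -0.0120 to 0.13 in all T-like, -0.12 to 0.0170 in naive-T-like, -0.0165 to 0.080 in Treg-like and -0.12 to 0.16 in effector-or-memory-T-like cells. It was -0.0159 in Treg-like cells of equal number, and in effector-or-memory-T-like cells 0.0279 with no filter and 0.0432 with no doublet removal. Il10 in Treg-like cells ran from -0.56 to 0.21 without 1 library and was 0.37 at resolution 0.5. In effector-or-memory-T-like cells resolution 2 gave Ifitm1 2.57, Ifi27l2a -1.16, Mcm5 -0.74, Atp5b -0.0821, S100a4 -0.0470 and Cd4 -0.0314. Without 1 library Il10 ran from -1.86 to 6.73 there, with 2 spleen UMIs. At resolution 2 the differences between classes were -0.89 for Klrk1, -1.86 for Ifitm2 and 0.32 for Id3 (Treg-like) and -1.05 for Ifitm2 (naive-T-like). With fry the adjusted p of lists that turned was 0.312 for Tfh in all T-like cells, 0.0839 for lipid handling and 0.00816 for Tfh, which passed, in Treg-like cells, and 0.369 for naive and recirculation in effector-or-memory-T-like cells. Without 1 library adjusted p ran from 0.151 to 0.998 for interferon in all T-like and 0.679 to 0.995 for Tfh in Treg-like cells. In effector-or-memory-T-like cells it ran from 0.427 to 0.803 for Tfh, 0.506 to 0.953 for cytotoxicity, 0.770 to 0.953 for chemokine receptors, 0.267 to 0.923 for cytokines and 0.197 to 0.908 for migration and adhesion. The Tfh-like share was 4.42 points higher at resolution 2. For thinned shares the difference without 1 library ran from -0.0340 to 0.123 for Il10 and -0.202 to 0.328 for Foxp3, and was -0.182 for Foxp3 at 2000 UMIs, -0.324 unthinned, and -3.01 for Cd69 unthinned. In the effector-or-memory class, with both fewer spleen cells and fewer spleen libraries, simulated changes of log2 1 were found in 22.2% of genes, against 79.8% in naive-T-like and 82.8% in Treg-like cells. Which of these limits it was not tested.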

Other observations

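The classes, clusters and genes of the next 2 paragraphs, the heat shock median in dendritic cell-like cells, the T cell marker ratio and the counts over other splits were chosen after the results had been seen; the other tests here were written before. In Th17-like cells 1174 genes passed by edgeR, 702 higher and 472 lower in vascular tissue, from 2 spleen libraries with 61 and 62 such cells (library 1 had 11 and was left out). Il17a rose from 329 to 2490 CPM within the class (2.91 ± 0.27, adjusted p = 6.6e-09) and Ifng from 24.6 to 106 CPM (2.08 ± 0.34). Litaf, a factor induced by bacterial products, rose by 5.15 ± 0.37 and Fosl2 by 4.92 ± 0.31, while Dtx1 (-3.78 ± 0.23) and Cd7 (-3.23 ± 0.27) fell. In interferon-responsive T-like cells 2356 genes passed, among them Anxa1, a brake on inflammation, at 5.47 ± 0.33, Cxcr6 at 4.74 ± 0.25, Ifng at 3.07 ± 0.47 and Dapl1 at -2.88 ± 0.26. Most spleen cells of this class lay in a cluster with Ly6c1, Oas2 and Ifit3 (8.20% of T-like cells, 0.700% in vascular tissue) and most vascular ones in a cluster with Mx1, Cxcl10 and Ifit3 (2.02% and 5.77%), so the class differs in make-up between the tissues. In cycling-like cells 594 genes passed, with Areg at 5.08 ± 0.34 and the chemokine receptor gene Ccr8 at 3.38 ± 0.28, and in Tfh-like cells 79, with the phosphatase gene Dusp14 at 3.07 ± 0.48 and the thymocyte gene Itm2a at -1.09 ± 0.20.

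Several clusters stood out by the markers they combined. A cluster of 324 cells, 95.7% of them vascular, had a Foxp3 UMI in 78.1%, Itgae in 50.9%, Il10 in 18.2% and Il17a in 13.3% of cells. The main vascular Treg-like cluster (1203 cells, 98.6% vascular) had Foxp3 in 75.4%, Areg in 72.6%, Klrg1 in 60.6% and Il1rl1 in 33.7%. The Th17-like cluster (937 cells) had Il17a in 42.5% and Ccr6 in 38.0%. A cluster of 466 cells led by Klrb1c and Il4, genes of natural killer T cells, had Il4 in 50.9% and Zbtb16, their transcription factor, in 33.9%, and another of 1101 cells was led by Cldn10, Sox4 and Myb, genes of immature cells (5.92% of spleen and 0.641% of vascular T-like cells). These shares are unthinned.

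Heat shock genes were higher in vascular cells of every class tested. Handling or digestion acting on every cell type could account for this, since the heat shock list had a median log2 difference of 1.23 in dendritic cell-like cells, where 11 of 12 members rose, and the same median with the 1 member without a spleen UMI at its bound. Free RNA of vascular T cells taken up with dendritic cell-like cells is argued against by 11 T cell markers, whose median level there was at most 0.0248 of that in T-like cells in any vascular library. General free RNA in the suspension stays open: the excess in dendritic cell-like cells was 0.506, 0.581 and 0.682 of that in T-like cells over 11 genes, and 0.682 lies within the range such RNA would give. A difference between the tissues in the animal was not tested, because enzyme digestion and tissue varied together.

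Naive-T-like cells differed between the tissues in 2095 genes. An effect of sampling common to all cell types may account for part: of 1732 genes called in naive-T-like cells and tested in dendritic cell-like cells, 81.9% had the same sign there, against 62.2% of the genes not called. Of 7567 genes tested in both, 382 were called in both, 370 of them with the same sign, where independent lists would share 157. Both cell types come from the same libraries, which adds to this overlap. An effect of the vascular tissue on all cell types in the animal would give the same overlap. It cannot be told apart from sampling here, because digestion and tissue varied together. Effector cells or their RNA among the vascular naive-T-like cells are argued against as the whole cause by 38.1% of 1218 rises, which exceeded the effector level. The median rise would need 77.4% of effector RNA, while 21 effector markers gave 0.635%. The latter is no independent measure, because clustering and naming had already set these cells apart from effector cells. A true difference of naive cells in the vascular tissue stays open and was not tested.

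The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 4890 genes in all T-like, 2095 in naive-T-like and 3218 in Treg-like cells by edgeR, and the highest of the other splits 0 in each, with 746, 968 and 555 genes at an unadjusted p under 0.05 against 6062, 3426 and 4091 in the real split. Each other split put libraries of both tissues in both groups, so a tissue difference widened the spread within groups. Low gene counts there were thus built into the design and do not bear on chance. DESeq2 was run on the real split alone. For gene lists the real split gave 17, 16 and 15, and the highest other split 16, 9 and 13. Only 1 split, the real one, reached the real value in each case, but for lists in all T-like and Treg-like cells other splits came close. The number of lists passing at the preset correlation thus hardly set the real grouping apart from a mixed one there. Mixed splits also keep part of the tissue difference, so the list counts do not bear on chance either.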
